A study of Mus musculus with 25 samples.

How the data were processed

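The series holds 25 droplet-based (10x Genomics) single-cell RNA libraries of mouse kidney. The deposited files are, for each library, a list of cell barcodes, a list of features and a matrix of raw UMI counts, so the values are unnormalised counts of molecules per gene and barcode. Per the labels, the authors counted with Cell Ranger 3.1.0 on mm10 and went on with Seurat 3.2.3. Per the file headers, the deposited matrices come from Cell Ranger 3.1.0 (13 libraries, 31057 features), 4.0.0 (8 libraries, 32289 features) and 6.1.2 (week 4 and control with dox, 32289 features). Library totals run from 7188526 to 43195047 UMIs, barcodes per library from 1726 to 5903 and median UMIs per barcode from 2385 to 7120. The 30410 genes in both feature lists were used, and they hold between 99.6 and 100% of the UMIs of each library. Intervals and floors cover counting error only.

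Cells were kept with at least 300 detected genes and at most 50% mitochondrial UMIs, which removed 20800 barcodes for mitochondrial content and 219 for few genes only. Scrublet in scanpy 1.11.5 scored doublets per library, and the top 0.8% per 1000 barcodes were left out. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 2) were used without integration. Clusters were named from cell type markers, some of which (Havcr1, Sox9, Fbp1 and others) also belong to gene lists tested later. The proximal tubule class joins proximal tubule-like clusters with injured tubule-like clusters that show tubule markers, and the mononuclear phagocyte class joins monocyte-like, macrophage-like and dendritic-like clusters. The largest cluster of the tubule class was 8 in controls (27.1%), right kidneys at 48 hours (15.0%) and day 12 (10.5%). It was 42 at 8 hours (19.8%), 23 at 24 hours (35.6%), 15 in left kidneys at 48 hours (14.0%), 17 at day 6 (11.0%), 16 at week 4 (34.3%) and 33 in control with dox (43.1%). No cluster was named thick ascending limb or principal cells. Cluster 31 (393 cells) showed 7 of 9 thick ascending limb and 5 of 8 principal cell markers, with Umod and Aqp2 among its leading genes, but mixed markers of other types and met no naming rule. As this left no such class and endothelial cells were under 20 in every library, 9 planned tests on these classes were not run. Clusters 31, 32, 44, 45 and 46 met no naming rule and were left out of every class. They held 0.99% of control cells, 23.8% at week 4 and 13.0% in control with dox.

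Raw counts were summed per library over the cells of a class. The main test was edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood fits, TMM scaling, filterByExpr with a minimum count of 10, and all 25 libraries in 1 fit with terms for group and feature-list version. In this way 12839 genes of the tubule class and 11693 of the phagocyte class were tested, and calls are at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Class shares were tested with edgeR on cell counts, with the library's total as offset and no TMM. Of 24 gene lists, 21 were tested with camera in limma 3.58.1 (preset correlation 0.01, on log2 CPM with a prior count of 2), beside camera with an estimated correlation and fry, adjusted over all planned tests. Fry asks whether a list's genes move on balance in 1 direction, without setting them against other genes. The lists of hemoglobin, sex-linked and transgene features served as checks. CPM are UMIs of a gene per 1000000 UMIs of the class in the library.

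Classes, tests, lists and alternatives were chosen before the data were examined, except those named as added. Genes are named by a rule: per tubule comparison the 8 largest rises and 8 largest falls (5 each for phagocytes) among called genes. They needed a mean of at least 20 CPM in 1 group, no overlap between the libraries of the groups, and a level in the class of at least 0.1 of the highest other class, a guard against free RNA in droplets. Levels for this limit were taken over all libraries, not over the groups compared. A gene that is high in only some groups therefore falls under it more easily. Mitochondrial, ribosomal, unnamed and sex-linked genes were left out. Up to 4 called members per list were added whatever their level elsewhere. Genes given here without comment kept their call when any 1 library of the 2 groups was left out. Gsta1, Serpina1a, Cyp4a12b, Cyp4a10, Cyp4a14, Cyp2a4, Saa1, Hspa1b and Acot1 belong to families of near-identical copies, between which short reads may be shared. Coordinates are from GENCODE vM21 on mm10.

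Replicate letters were checked for pairing. At 48 hours libraries of the same letter correlated across genes after removal of group means (0.374 to 0.587, and 0.235 to 0.344 after the feature-list term). Left and right were therefore also compared with letter as a block shared by the libraries of all groups, which gave 122 calls in place of 119. The paired fit of only the 2 sides, added after seeing the data, called many more genes. In other comparisons letters are shared labels without such a relation in every pair after that term. For 3 libraries against 3, the fit was repeated on the 10 splits of the 6 libraries. The test was also checked on simulated data: in the tubule class 8.3, 29.9 and 74.2% of genes shifted 1.5-fold, 2-fold and 4-fold were called, with 2 false calls among 12289 other genes. For class shares, a 4-fold shift simulated for 24 hours against control was called in 18 of 50 runs, with 8 false calls of 350 possible. Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, no feature-list term, letter as a block, only the 2 groups in the fit, other limits on cells, a coarser clustering, narrower and wider classes and leaving out each library in turn. Added after seeing the data were clusters 44 and 45 in the tubule class, fits without the Cell Ranger 6.1.2 libraries or with the shorter feature list alone, the paired fit of only the 2 sides, cluster 37 counted as dendritic cells in the shares, all barcodes as the total of the shares and the comparison of week 4 with control with dox.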

Results

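Mouse kidney cells were profiled by droplet-based single-cell RNA sequencing after unilateral ischemia-reperfusion injury, in which the blood supply of 1 kidney is interrupted and then restored. The 25 libraries fall into 9 groups. Control, 8 hours, 24 hours, 48 hours left, 48 hours right, day 6 and day 12 hold 3 libraries each (a, b and c), and week 4 and control with dox hold 2 each (a and b). The labels do not say which kidney was injured, nor what the doxycycline of the second control group was meant to switch on. Nothing says that replicates were separate animals, so every p-value measures spread between libraries. In the main fit that spread is pooled over all 9 groups, so it is not the spread of the compared groups alone. Values per group are means ± SD over its libraries, with n = 3 unless week 4 or control with dox (n = 2) is named, and errors of log2 fold changes are standard errors.

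Library totals of unique molecular identifiers (UMIs) were 20584505, 29706339 and 28956012 in controls a to c. They were 27367169, 25293587 and 34149095 at 8 hours and 26167312, 18669280 and 30531916 at 24 hours. At 48 hours they were 29299533, 18992604 and 7188526 on the left and 22404787, 26231243 and 12007319 on the right. Day 6 gave 14279681, 18044396 and 25652453, and day 12 gave 14327564, 13768306 and 23289105. Week 4 gave 27901028 and 15202328, and control with dox 25514794 and 43195047. Of 90134 barcodes, 69115 passed the limits on genes and mitochondrial UMIs, and 66998 remained after removal of 2117 probable doublets.

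Proximal tubule cells made up most of each group, and monocyte-like and neutrophil-like cells were more frequent at 24 hours and in left kidneys at 48 hours. The proximal tubule class held 89.4 ± 5.34% of control cells, 71.9 ± 15.8% at 24 hours, 73.8 ± 8.16% in left kidneys at 48 hours and 93.3 ± 4.00% in right ones. Monocyte-like cells rose from 0.956 ± 0.361% of control cells to 14.5 ± 11.8% at 24 hours (log2 ratio 3.92 ± 0.92, adjusted p = 0.00195). They were 17.5 ± 6.32% of cells in left kidneys at 48 hours against 0.524 ± 0.033% in right ones (log2 ratio 5.05 ± 0.95, adjusted p = 0.000386). Left kidneys exceeded controls as well, by 4.19 ± 0.93 (adjusted p = 0.00221). The naming rule puts cluster 37 among these cells, although dendritic cell genes such as Cd209a and Ccl17 lead it, and it gave 53.1% of them in controls, 6.8% at 24 hours and 3.9% in left kidneys. With this cluster counted as dendritic cells, a setting added after seeing the data, the log2 ratios were 4.81 ± 0.92 at 24 hours, 5.13 ± 0.93 for left kidneys and 5.41 ± 0.93 for left against right (adjusted p = 0.000453, 0.000243 and 0.000128). Neutrophil-like cells were found in 0 of 6975 control cells, which allows a share of up to 0.043%, against 0.836 ± 0.226% at 24 hours (adjusted p = 0.00195). In left kidneys at 48 hours they were 0.784 ± 0.797% of cells, above controls (adjusted p = 0.00287) and above the 0.040 ± 0.038% of right kidneys (log2 ratio 4.01 ± 1.09, adjusted p = 0.00889). The cells counted are those left after the limit on mitochondrial UMIs, which removed 8.57 ± 6.74% of barcodes on the left and 30.5 ± 4.26% on the right. With all barcodes as the total, a setting added after seeing the data that takes the removed ones as neither class, the log2 ratios of left to right were 5.48 ± 1.01 and 4.33 ± 1.10 (adjusted p = 0.000312 and 0.00575), and a higher share of B lineage cells on the left was called as well (1.96 ± 0.72, adjusted p = 0.039). What the removed cells were was not tested.

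Day 6 and day 12 held more phagocytes on average than controls, but no class share passed the test at these times. On simulated data the share test called a 4-fold shift in 18 of 50 runs, so a share without a call may still have changed. Monocyte-like cells were 5.01 ± 1.03% at day 6 (adjusted p = 0.0999) and 4.99 ± 4.43% at day 12 (adjusted p = 0.059), of which cluster 37 gave 45.8% and 63.8%. With this cluster counted as dendritic cells they were 2.76 ± 0.359% and 1.82 ± 1.49%, against 0.431 ± 0.045% in controls, and 0 shares were called at either time. Macrophage-like cells were 12.2 ± 4.86% and 17.3 ± 14.5% at these times, against 7.54 ± 4.79% in controls. At 8 hours and in right kidneys at 48 hours edgeR called 0 class shares. Week 4 and control with dox had lower shares of cells named monocyte-like than controls, at 0.062 ± 0.027% and 0.011 ± 0.016%. The log2 ratios were -3.79 ± 1.22 and -5.74 ± 1.44 (adjusted p = 0.0123 and 0.0035). With cluster 37 counted as dendritic cells they were -3.40 ± 1.31 and -4.49 ± 1.41 (adjusted p = 0.0291 and 0.014). These shares rest on 4 and 1 cells, against 64 in controls. Both groups were counted with another software version than controls, so time or doxycycline cannot be told apart from counting. Cluster 46, with macrophage markers but no class name, held 117 cells at week 4, 45 in control with dox and 0 in controls. The phagocyte class held 109, 202 and 597. Whether cells left out in this way lowered the shares was not tested. Of the 2 classes called between left and right kidneys at 48 hours, 1 was called without left library a. Without day 12 library b, 3 shares were called at day 12. The monocyte call at week 4 was lost without week 4 library a or b (adjusted p = 0.0699 for both). Without week 4 library a, 1 of the 5 calls at week 4 was left, and without control library a control with dox had 5 calls in place of 3. It had 4 with cluster 37 counted as dendritic cells and 2 with all barcodes as the total, where the lower share of B lineage cells was no longer called (adjusted p = 0.0751).

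**Figure D1:**
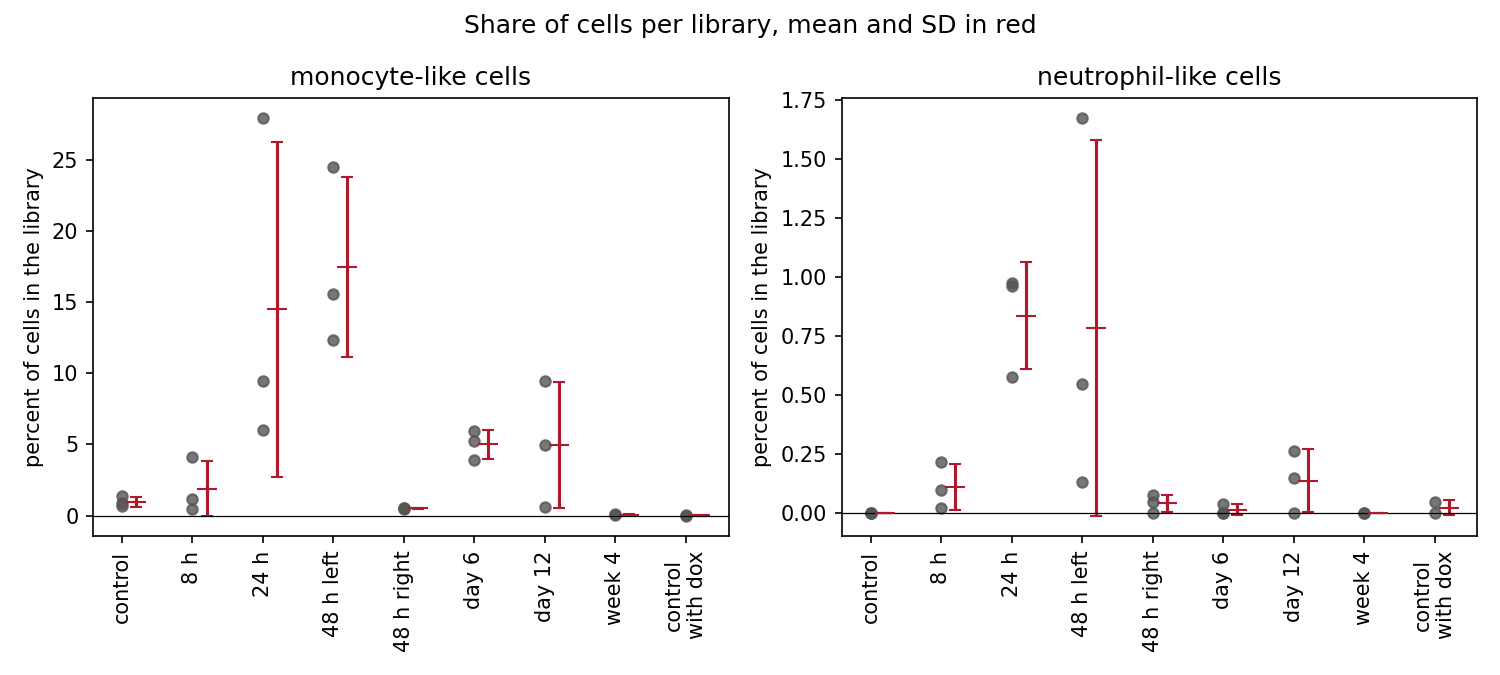
Share of monocyte-like (left) and neutrophil-like (right) cells among all cells of a library, in percent, 1 grey point per library, with the group mean and SD in red. Monocyte-like cells reach 14.5% at 24 hours and 17.5% in left kidneys at 48 hours, against 0.956% in controls.

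**Figure D2:**
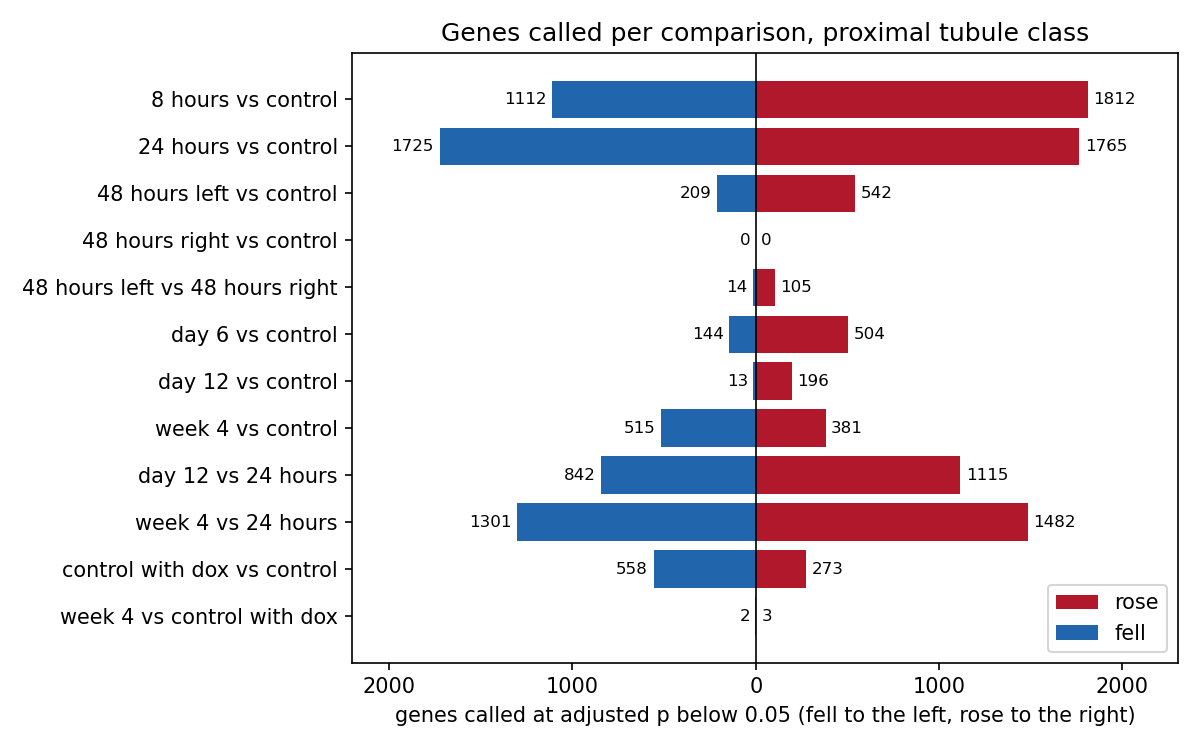
Number of genes called in the proximal tubule class at an adjusted p below 0.05, fallen to the left of 0 and risen to the right, for 12 comparisons. The total runs from 0 in right kidneys at 48 hours to 3490 at 24 hours (1765 rises and 1725 falls), and rises alone are most numerous at 8 hours (1812).

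The comparison of 8 hours with control asks how tubule cells look at the earliest time after injury. Genes of injury, stress and inflammation were among the rises in the proximal tubule class, although the 3 libraries stood apart. Library a held 94.4% of the cells of cluster 28, whose leading genes include Krt20, Fosl1 and Plin2, library b 87.9% of cluster 25, led by Iigp1 and Pigr, and library c 98.3% of cluster 42, led by Sox4 and Mt1. Krt20, a keratin of the intermediate filaments, stood at 182 ± 271 CPM (UMIs of the gene per 1000000 UMIs of the class) against 0.065 ± 0.075 in controls (log2 fold change 11.96 ± 2.29, adjusted p = 0.00257), with 494, 1.5 and 50.7 CPM in libraries a to c. The AP-1 subunit Fosl1 had no count in controls and was at least 800-fold higher, measured against 3 counts over the control group. Sox9, a transcription factor of developing tubules, reached 24.4 ± 22.6 CPM, with 1 UMI in the controls. The lipid droplet protein Plin2 rose by 6.42 ± 1.14 on the log2 scale and Sphk1, which makes sphingosine 1-phosphate, by 6.64 ± 0.80 (adjusted p = 0.00156 and 0.000136). Cdkn1a, a cyclin-dependent kinase inhibitor, and Hmox1, which degrades haem, rose by 4.03 ± 0.52 and 3.57 ± 0.43 (adjusted p = 0.00019 and 0.000131). Among the falls, the succinate receptor gene Sucnr1 changed by -2.38 ± 0.43 and the peroxisomal oxidase gene Hao2 by -1.64 ± 0.28 (adjusted p = 0.00126 and 0.000605).

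In all, 2924 of 12839 tested genes changed at 8 hours, 1812 up and 1112 down. Of 20 measured tubular injury markers, 15 rose (17 adjusted over the list alone), and the list was called by camera (adjusted p = 4.84e-09, adjusted p = 0.259 with an estimated correlation). Of 15 NF-kB and chemokine genes, 13 rose (14 adjusted over the list alone), among them the neutrophil attractant Cxcl2 (camera adjusted p = 6.61e-09, adjusted p = 0.181 with an estimated correlation). Of 10 acute phase and metallothionein genes 6 rose (9 adjusted over the list alone), with Fgg, a fibrinogen chain, at 158 ± 121 CPM against 9.29 ± 2.75 (camera adjusted p = 0.000218, adjusted p = 0.248 with an estimated correlation). Of 14 p53 targets 7 rose (8 adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.319 with an estimated correlation). Of 18 nuclear genes of oxidative phosphorylation 1 fell and 0 adjusted over the list alone, although camera called the list downward (adjusted p = 0.000111, adjusted p = 0.456 with an estimated correlation). Of the rises 25.1%, against 11.3% of tested genes, were of genes whose level in the class was under 0.1 of that in another class, including 7 of the 15 injury markers and 7 of the 13 chemokine genes. Here and below these levels are over all libraries. Genes that rise in 1 group only fall under the limit more easily, so such shares do not measure free RNA. The count of 2924 became 1711 without control library c, 1720 without control b and 1707 without 8 hour library a. With only these 2 groups in the fit it was 1, so nearly all calls ended, among them those of Krt20, Sox9, Plin2, Sphk1, Cdkn1a, Hmox1, Sucnr1 and Hao2. The main fit pools the spread of a gene over all groups, and the 8 hour libraries vary more than the controls. Their biological coefficient of variation, the edgeR measure of spread between libraries, was 0.452 against 0.203. The p-values of the main fit therefore do not measure the spread of the 8 hour libraries alone.

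At 24 hours the proximal tubule class had gained injury and acute phase transcripts and lost transcripts of several transporters. Havcr1, the kidney injury molecule that lets tubule cells take up debris, rose from 2.21 ± 1.15 to 327 ± 67.0 CPM (log2 fold change 7.11 ± 1.36, adjusted p = 0.00147). Spp1, which encodes osteopontin, rose from 193 ± 9.84 to 6517 ± 1993 CPM (4.95 ± 0.50, adjusted p = 3.89e-06). The fibrinogen genes Fgb and Fgg rose by 6.91 ± 1.07 and 5.67 ± 0.86 (adjusted p = 0.000285 and 0.000218). The brush border protease gene Mep1b fell from 68.0 ± 18.5 to 1.36 ± 0.96 CPM (-5.70 ± 0.99, adjusted p = 0.000693). Slc22a7, an organic anion transporter, and Inmt, a methyltransferase, changed by -4.94 ± 1.04 and -4.36 ± 0.47 (adjusted p = 0.00269 and 7.06e-06). Some of the genes that fell lead single clusters of the class, Slc22a7 and Mep1b cluster 4, and Slc7a13 and Kap cluster 8. Cluster 8 was the largest of the class in controls (27.1%), and cluster 23 at 24 hours (35.6%). The groups thus held unlike mixes of clusters. Changes within 1 kind of tubule cell were not tested, here or at other times. In the mm10 genome, Havcr1 (ENSMUSG00000040405) lies on chromosome 11 from 46735080 to 46779578, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050, and Inmt (ENSMUSG00000003477) on chromosome 6 from 55170626 to 55175043.

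The class changed in 3490 of 12839 genes at 24 hours, 1765 up and 1725 down. Of 27 proximal tubule transporters 17 fell and 1 rose (19 and 1 adjusted over the list alone), the amino acid transporter gene Slc7a13 by -3.61 ± 0.63 (camera adjusted p = 6.61e-09, adjusted p = 0.284 with an estimated correlation). Of 6 gluconeogenesis genes 4 fell (6 adjusted over the list alone), among them Fbp1 by -1.81 ± 0.23 and G6pc, the last enzyme of glucose release, by -3.09 ± 0.65 (camera adjusted p = 0.000521, adjusted p = 0.336 with an estimated correlation). Of 18 nuclear oxidative phosphorylation genes 8 fell (9 adjusted over the list alone; camera adjusted p = 6.87e-05, adjusted p = 0.447 with an estimated correlation), and of 27 fatty acid oxidation genes 7 fell (7 adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.783 with an estimated correlation). Of 5 androgen-regulated genes 4 fell (5 adjusted over the list alone), with Kap, the kidney androgen-regulated protein gene, going from 52375 ± 1723 to 11123 ± 2909 CPM (camera adjusted p = 0.000358, adjusted p = 0.23 with an estimated correlation). Injury markers rose in 17 of 20 cases (19 adjusted over the list alone; camera adjusted p = 3.81e-13, adjusted p = 0.18 with an estimated correlation), and acute phase genes in 9 of 10 (9 adjusted over the list alone; camera adjusted p = 1.23e-06, adjusted p = 0.136 with an estimated correlation). Of the 1765 rises 24.5% were of genes under 0.1 of their level in another class, including 8 of the 17 injury markers and 2 of the 9 acute phase genes. Leaving out 1 library moved the count to between 2428 and 2767. In the libraries with the shorter feature list, an added setting that keeps 1 control library (a), it was 440.

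**Figure D3:**
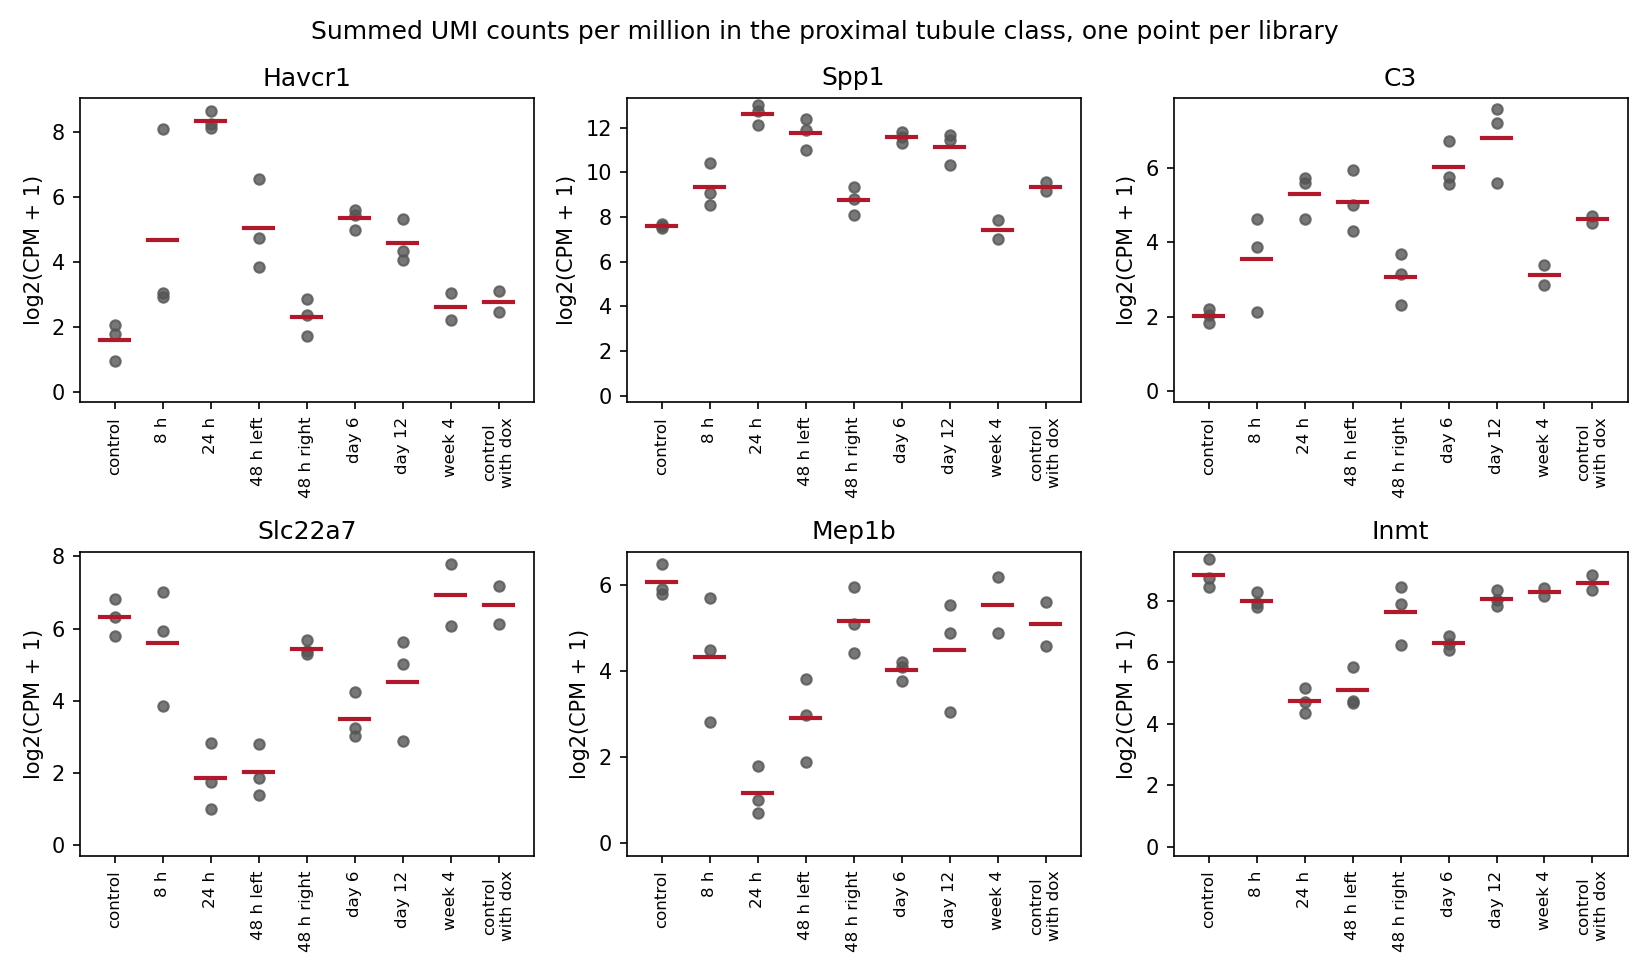
Level of 6 genes in the proximal tubule class, as log2(CPM + 1) of summed UMIs, 1 grey point per library and a red line at the group mean of these logs. Havcr1, Spp1 and C3 are at their lowest in controls or week 4, and Slc22a7, Mep1b and Inmt at their lowest at 24 hours.

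At 48 hours each side was compared with control and with the other side, which sets the left and the right kidney apart at a time when the labels give both. In left kidneys, genes of injury and of the cell cycle were among those higher than in controls. Spp1 stood at 3747 ± 1684 CPM (log2 fold change 4.19 ± 0.48, adjusted p = 7.54e-05). Cfi and C3, both of the complement system, rose by 4.01 ± 0.49 and 3.55 ± 0.63 (adjusted p = 0.000134 and 0.00331). Of 19 cell cycle genes 16 rose (17 adjusted over the list alone), with Top2a, which untangles DNA, at 16.3 ± 7.24 CPM against 0.429 ± 0.452, and Cenpf, a kinetochore protein gene, at 10.9 ± 1.0 against 0.294 ± 0.318 (camera adjusted p = 1.74e-19, adjusted p = 0.0739 with an estimated correlation). Of these 16 genes, 12, Top2a and Cenpf among them, were under 0.1 of their level in another class. The class also holds cluster 11 (497 cells), named proximal tubule-like and led by cell cycle genes such as Hmmr, Cdk1 and Top2a. Left kidneys at 48 hours gave 39.4% of its cells, the largest share of any group. Falling under the limit therefore does not show that these transcripts came from another class. Injury markers rose in 10 of 20 cases (17 adjusted over the list alone; camera adjusted p = 1.05e-15, adjusted p = 0.136 with an estimated correlation), 8 of the 10 being under the same limit. Inmt and Kap fell (-3.85 ± 0.46 and -1.86 ± 0.28, adjusted p = 0.000119 and 0.000642), and transporters fell in 4 of 27 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000751, adjusted p = 0.561 with an estimated correlation). Of all tested genes 542 rose and 209 fell, and 47.4% of the rises were under 0.1 of another class. This count of 751 was 269, 344 and 332 without control libraries a, b and c, and 258 and 353 without left libraries b and c.

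In right kidneys at 48 hours no gene of the class passed the test against controls. By edgeR 0 genes were called, with 541 at an unadjusted p under 0.05, and DESeq2 called 9. With no filter on low counts edgeR called 121. Of 19 cell cycle genes 0 were called over all genes and 7 rose adjusted over the list alone, and camera called the list upward (adjusted p = 1.41e-10, adjusted p = 0.18 with an estimated correlation). Camera also called the immediate early list downward with 0 of 15 members called by edgeR (adjusted p = 0.00175, adjusted p = 0.588 with an estimated correlation).

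Set directly against right kidneys, left ones were higher for some injury and cell cycle genes. Spp1 was at 3747 ± 1684 CPM on the left and 453 ± 185 on the right (log2 fold change 3.0 ± 0.46, adjusted p = 0.00316). Cpn1, a subunit of a plasma carboxypeptidase, was at 311 ± 37.8 against 79.5 ± 12.4 CPM (1.93 ± 0.21, adjusted p = 2.81e-05), and Cyp4a12b, a fatty acid hydroxylase gene, was higher by 2.77 ± 0.31 (adjusted p = 3.55e-05). Lad1, which encodes a basement membrane protein, was higher by 1.49 ± 0.19 (adjusted p = 0.000243). Inmt was lower on the left (-2.69 ± 0.44, adjusted p = 0.00447), and its call was lost without right library a (adjusted p = 0.051) and with only the 2 groups in the fit (adjusted p = 0.28). Of 20 injury markers 3 rose (13 adjusted over the list alone; camera adjusted p = 4.33e-20, adjusted p = 0.0739 with an estimated correlation), and of 19 cell cycle genes 5 rose (18 adjusted over the list alone; camera adjusted p = 3.23e-17, adjusted p = 0.0739 with an estimated correlation). Of these, 2 of the 3 and 4 of the 5 were under 0.1 of their level in another class, as were 60.0% of all rises. With letter as a block shared by the libraries of all groups, the calls of the cell cycle genes Rrm2 and Mcm5 (adjusted p = 0.0684 and 0.0699), Gsta4 (0.0502), Irx3 (0.053) and Csad (0.053) were lost. That block does not pair the kidneys alone. The paired fit of only the 2 sides, added after seeing the data, called many more genes. It lost the calls of Cyp2a4 and Kap in phagocytes, but not these. The 119 calls, 105 up and 14 down, became 37 and 62 without left libraries b and c and 19, 21 and 54 without right a, b and c.

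At day 6 C3, Cfi, Fgg, Cp, Vcam1 and Cdk1 were among the genes above control, and Inmt, Nat8f1 and Nr1d1 among those below it. The cells of this time are unevenly spread over its libraries: library c held 75.4% of all cells of cluster 24, led by Plin2, Cxcl10 and C3, and 66.2% of cluster 17, the largest of the class at day 6. C3, the central complement component, rose by 4.42 ± 0.65 on the log2 scale and Cfi, which inactivates it, by 3.93 ± 0.49 (adjusted p = 0.000806 and 0.000167). Fgg and Cp, the gene of the copper carrier ceruloplasmin, rose by 4.72 ± 0.82 and 4.21 ± 0.68 (adjusted p = 0.00316 and 0.0017). Vcam1, a leukocyte adhesion molecule, stood at 22.1 ± 9.14 CPM against 0.084 ± 0.021 (adjusted p = 0.000335), and Cdk1, the mitotic kinase, at 10.0 ± 1.03 against 0.606 ± 0.318 (adjusted p = 0.000113). Both were under 0.1 of their level in another class. Inmt, Nat8f1, an acetyltransferase gene, and Nr1d1, a repressor of the circadian clock, fell (-2.44 ± 0.43, -1.92 ± 0.31 and -2.84 ± 0.54, adjusted p = 0.00253, 0.001 and 0.00445).

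At day 6, 504 genes rose and 144 fell. Of 15 NF-kB and chemokine genes 10 rose (15 adjusted over the list alone; camera adjusted p = 1.74e-15, adjusted p = 0.0739 with an estimated correlation), and of 10 acute phase genes 6 (7 adjusted over the list alone; camera adjusted p = 4.84e-09, adjusted p = 0.0739 with an estimated correlation). Injury markers rose in 11 of 20 cases (17 adjusted over the list alone; camera adjusted p = 2.71e-19, adjusted p = 0.0811 with an estimated correlation) and cell cycle genes in 12 of 19 (16 adjusted over the list alone; camera adjusted p = 3.74e-16, adjusted p = 0.0739 with an estimated correlation). Genes under 0.1 of their level in another class made up 44.6% of all rises, with 6 of the 10 chemokine genes, 2 of the 6 acute phase genes, 6 of the 11 injury markers and 9 of the 12 cell cycle genes. The count of 648 became 345, 254 and 311 without control libraries a, b and c, and 377 and 329 without day 6 libraries b and c.

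At day 12 C3, Cfi, Cp and Serpina10 were among the genes above control in the proximal tubule class, and 13 genes were below it. C3 (ENSMUSG00000024164, chromosome 17 from 57203970 to 57228136) was at 128 ± 73.5 CPM against 3.08 ± 0.51 (log2 fold change 5.30 ± 0.67, adjusted p = 0.000342). Spp1 was at 2458 ± 1057 CPM (3.54 ± 0.47, adjusted p = 0.000328). Serpina10, a protease inhibitor of the clotting system, rose by 6.22 ± 0.83, Cfi by 4.11 ± 0.49 and Cp by 4.40 ± 0.69 (adjusted p = 0.00053, 0.000157 and 0.00236). Vcam1 stood at 40.4 ± 19.9 CPM against 0.084 ± 0.021 (adjusted p = 0.000179), under 0.1 of its level in another class. Of 20 injury markers 5 rose (16 adjusted over the list alone; camera adjusted p = 7.96e-22, adjusted p = 0.0739 with an estimated correlation), 2 of them under that limit. Of 15 NF-kB and chemokine genes 7 rose (12 adjusted over the list alone; camera adjusted p = 3.61e-17, adjusted p = 0.0739 with an estimated correlation), 3 of them under the limit, and of 10 acute phase genes 3 (7 adjusted over the list alone; camera adjusted p = 1.6e-09, adjusted p = 0.0739 with an estimated correlation). In the cell cycle list edgeR called 0 of 19 genes, over all genes or adjusted over the list alone (camera adjusted p = 0.576). The 209 calls were 196 rises, 48.5% of them under the limit, and 13 falls. They became 118, 54 and 77 without control libraries a, b and c, and 109 and 59 without day 12 libraries a and c.

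Day 12 against 24 hours asks how far the class had moved on from the early injured state. Some transport and fatty acid oxidation genes and all 6 measured gluconeogenesis genes were higher at day 12. Mep1b rose by 4.42 ± 0.95 on the log2 scale, Ugt2b37, a glucuronosyltransferase gene, by 3.68 ± 0.33 and Inmt by 3.34 ± 0.45 (adjusted p = 0.00686, 3.05e-06 and 0.000178). Of 27 transporters 12 rose (18 up and 1 down adjusted over the list alone; camera adjusted p = 1.08e-07, adjusted p = 0.305 with an estimated correlation), with Slc5a8, a monocarboxylate carrier, at 105 ± 12.6 CPM against 18.1 ± 7.08. The 6 gluconeogenesis genes all rose (6 adjusted over the list alone; camera adjusted p = 1.41e-05, adjusted p = 0.259 with an estimated correlation), Fbp1 standing at 1300 ± 98.7 CPM against 419 ± 59.0. Of 27 fatty acid oxidation genes 12 rose (16 adjusted over the list alone; camera adjusted p = 2.19e-07, adjusted p = 0.437 with an estimated correlation). Havcr1 was at 24.7 ± 12.5 CPM at day 12 (log2 fold change -3.68 ± 1.13, adjusted p = 0.0396), and this call was lost whichever library of the 2 groups was left out. Without 24 hour libraries a, b and c its adjusted p was 0.0666, 0.0769 and 0.0792, and without day 12 a, b and c 0.0726, 0.118 and 0.123. Vcam1 was 5.20 ± 0.78 higher at day 12 than at 24 hours (adjusted p = 0.000618). In all, 1115 genes rose and 842 fell. The 1957 calls became 1073 and 977 without day 12 libraries a and b, and 1109, 1156 and 1165 without 24 hour libraries a, b and c.

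Week 4 and control with dox differ from all other groups in the software that made their counts, Cell Ranger 6.1.2, so time or doxycycline cannot be told apart from counting in any comparison of them with the other groups. Cells rich in Malat1, a long non-coding RNA kept in the nucleus, were almost missing from their proximal tubule class, at 0.195 ± 0.082% and 0.355 ± 0.220% of it against 16.7 ± 3.90% in controls. In these libraries the cells lay in clusters 44 and 45, which carry proximal tubule genes but met no rule for a class name. Clusters 44 and 45 held 11.3% and 9.88% of week 4 cells and 0.986% and 11.1% of control with dox cells. With both added, Malat1-rich cells were 23.6 ± 7.86% and 13.2 ± 2.08% of the class. The limit of 1% of UMIs for such cells, and the choice of these clusters, were made after seeing the data.

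**Figure D4:**
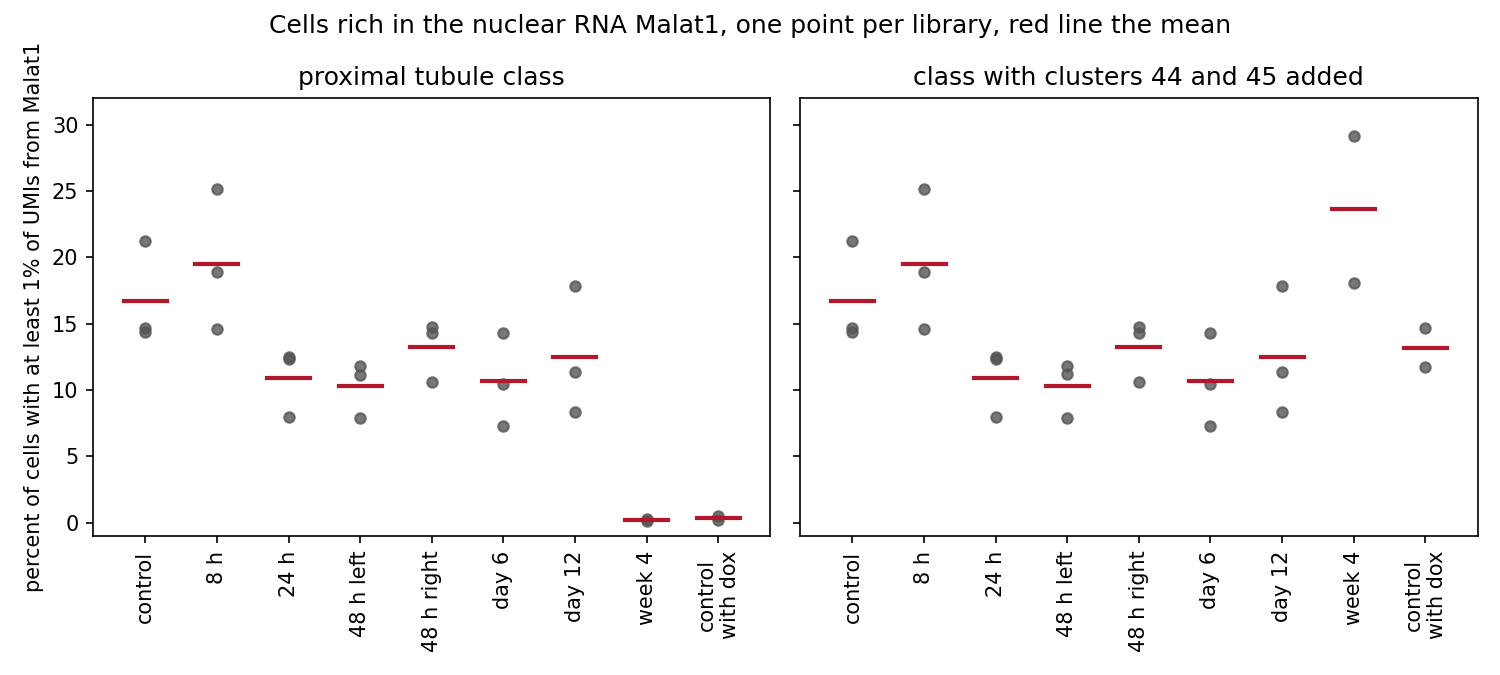
Percent of proximal tubule cells with at least 1% of UMIs from Malat1, 1 grey point per library and a red line at the group mean, in the class as defined (left) and with clusters 44 and 45 added (right). Week 4 and control with dox are near 0 on the left and at 23.6% and 13.2% on the right.

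Against control, some fatty acid oxidation genes were higher at week 4, and the nuclear RNAs Malat1, Neat1 and Kcnq1ot1 were called lower only while clusters 44 and 45 stayed out of the class. Of 27 fatty acid oxidation genes 16 rose, and 9 with these clusters added (21 adjusted over the list alone; camera adjusted p = 1.3e-15, adjusted p = 0.23 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase (ENSMUSG00000066072, chromosome 4 from 115518264 to 115533649), was at 1186 ± 25 CPM against 77.3 ± 28.8 (log2 fold change 3.67 ± 0.78, adjusted p = 0.0086, but 0.0664 without week 4 library a). The acyl-CoA thioesterase gene Acot1 and Cpt2, of the mitochondrial carnitine shuttle, rose by 3.54 ± 0.65 and 1.89 ± 0.30 (adjusted p = 0.00281 and 0.000366). The largest rises were of Camk1d, Il31ra and Cmss1, Cmss1 going from 9.57 ± 1.52 to 2796 ± 323 CPM. Malat1 was at 370 ± 43.4 CPM against 28611 ± 9609 (-6.20 ± 0.49, adjusted p = 3.69e-08), and with clusters 44 and 45 added its fold change was 0.01 ± 0.38 (adjusted p = 0.994). Neat1 and Kcnq1ot1, also nuclear, were lower in the same way (-5.58 ± 0.39 and -8.14 ± 0.83, adjusted p = 5.78e-09 and 6.59e-06), and with the clusters added both calls ended (-0.60 ± 0.31 and -0.57 ± 0.43, adjusted p = 0.154 and 0.365). Of 15 immediate early genes 6 fell, and 7 with the clusters added (11 adjusted over the list alone; camera adjusted p = 6.9e-08, adjusted p = 0.305 with an estimated correlation). Of 20 injury markers 1 rose (2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.29). The 381 rises and 515 falls, 896 in all, became 597 and 474 without control libraries a and c, 217 and 263 without week 4 libraries a and b, and 3719 with both clusters added.

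Relative to 24 hours, week 4 showed 1482 rises and 1301 falls. Slc5a8 rose by 3.98 ± 0.51 and Slc7a13 by 3.67 ± 0.69 on the log2 scale (adjusted p = 4.72e-05 and 0.00158), and Fgb fell by 6.38 ± 1.29 (adjusted p = 0.00272). Of 27 transporters 17 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 4.84e-09, adjusted p = 0.283 with an estimated correlation), and of 27 fatty acid oxidation genes 22 rose (25 adjusted over the list alone; camera adjusted p = 4.14e-14, adjusted p = 0.254 with an estimated correlation). Injury markers fell in 12 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 2.48e-08, adjusted p = 0.283 with an estimated correlation), and p53 targets fell in 9 of 14 (11 adjusted over the list alone; camera adjusted p = 1.79e-05, adjusted p = 0.135 with an estimated correlation). The 2783 calls became 1814 without 24 hour library c, 1258 and 1244 without week 4 libraries a and b, and 5368 with clusters 44 and 45 added.

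Control with dox differed from control in 273 rises and 558 falls. As at week 4, Camk1d, Il31ra and Cmss1 led the rises, Cmss1 at 833 ± 19.3 CPM, and Malat1 was among the falls at 299 ± 27.1 CPM (log2 fold change -6.48 ± 0.50, adjusted p = 2.82e-08), a call that ended with clusters 44 and 45 added (-0.31 ± 0.38, adjusted p = 0.598). Socs2, a brake on cytokine signalling, rose by 2.80 ± 0.52 (adjusted p = 0.00299). Fatty acid oxidation genes rose in 5 of 27 cases, and in 2 with these clusters added (20 adjusted over the list alone; camera adjusted p = 2.86e-11, adjusted p = 0.293 with an estimated correlation), and immediate early genes fell in 4 of 15, and in 3 with the clusters added (9 adjusted over the list alone; camera adjusted p = 1.19e-05, adjusted p = 0.437 with an estimated correlation). The 831 calls became 474 without control library c, 279 and 211 without dox libraries a and b, and 3209 with clusters 44 and 45 added. Week 4 set against control with dox, a comparison added after the shared counting software was seen, gave 5 calls of 12839 genes, 3 up and 2 down, with 504 at an unadjusted p under 0.05. The rises were of Cdk8, Cmss1 and Gphn, by 1.80 ± 0.29, 1.74 ± 0.29 and 1.49 ± 0.21 (adjusted p = 0.0146, 0.0146 and 0.00717). These 3 genes had a median span of 305 kb, against 22.3 kb for all tested genes. Whether introns counted in unequal measure between the libraries gave these rises was not tested. With clusters 44 and 45 added Cdk8 and Cmss1 kept their calls (1.40 ± 0.24 and 1.78 ± 0.29, adjusted p = 0.0335 for both), while Gphn was at 0.43 ± 0.21 (adjusted p = 1.0). With all cells summed Cdk8, Cmss1 and Gphn were at 1.32 ± 0.29, 1.69 ± 0.32 and 0.35 ± 0.30 (adjusted p = 0.461, 0.106 and 1.0), none of them called. That count was 0 without control with dox library a, 1 without dox library b, and 3 and 1 without week 4 libraries a and b, and DESeq2 called 13 genes, of which 30.8% rose against 60.0% by edgeR.

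In mononuclear phagocytes, Arg1, Pdpn, Timp1 and Cxcl3 were among the genes higher at 24 hours than in controls. Arg1, an arginase gene (ENSMUSG00000019987, chromosome 10 from 24915221 to 24927484), was at 642 ± 277 CPM with no count in controls, at least 1140-fold higher against 3 counts over the control group. Pdpn, the gene of the membrane glycoprotein podoplanin, and Timp1, an inhibitor of matrix proteases, also had no control counts and were at least 187-fold and at least 59.6-fold higher. Cxcl3, a neutrophil attractant, stood at 110 ± 14.0 CPM with 1 UMI in controls. The strongest falls were of genes of the proximal tubule, such as Slc7a13 (-6.78 ± 1.27), Inmt (-5.88 ± 0.71) and Ttr (-6.05 ± 0.80), with adjusted p = 0.00242, 8.6e-05 and 0.00024. Inmt and Slc7a13 were also lower at this time in the tubule cells themselves, at 26.5 ± 8.06 and 44.4 ± 23.8 CPM. Of 11693 tested genes 1081 rose and 1074 fell, so 50.2% rose, and 39.2% with the relative log expression scaling. In controls the macrophage-like cluster 21 held 64.2% of the class. At 24 hours the monocyte-like cluster 35, with Fn1, Arg1 and Ccl2 among its leading genes, held 36.8%. The comparison thus sets unlike mixes of phagocytes against each other, and changes within 1 kind of phagocyte were not tested. The 2155 calls became 1228, 1424 and 1182 without control libraries a, b and c, and 1203 and 1056 without 24 hour libraries a and c.

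Phagocytes of left and right kidneys at 48 hours differed in 604 genes higher and 494 lower on the left. Timp1 had no count on the right and was at least 49.3-fold higher on the left. Rnase2a, a ribonuclease gene of the eosinophil family, was at 188 ± 108 CPM with 1 UMI on the right, a call that was lost without right library b (adjusted p = 0.068). Inmt and the organic anion transporter gene Slco1a1 were lower on the left (-5.97 ± 0.86 and -3.78 ± 0.81, adjusted p = 0.000522 and 0.00958). Inmt was also lower in left tubule cells (-2.69 ± 0.44), and cluster 19, which had 10 of 14 proximal tubule markers at 0.2 or more of the highest cluster's level, held 25.5% of the class on the right and 7.94% on the left. The monocyte-like cluster 35 held 45.8% of the class on the left and the macrophage-like cluster 21 49.9% on the right, so the sides hold unlike mixes of phagocytes. Of the calls 55.0% were rises, and 44.2% with the relative log expression scaling. The 1098 calls became 613 and 378 without left libraries a and c, and 522, 463 and 570 without right a, b and c.

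At week 4 the phagocyte class held 198875 UMIs in all, and 79 genes rose and 139 fell against control. The clusters behind it differ from those of controls: cluster 19 held 93.6% of the 109 cells at week 4 and 17.4% of those in controls, where cluster 21 held 64.2%. Cluster 46, which showed 6 of 6 macrophage markers but met no naming rule, had 117 cells at week 4 and 0 in controls and was left out. Cmss1 rose from 7.37 ± 6.17 to 1901 ± 56.1 CPM (7.59 ± 0.45, adjusted p = 5.38e-12), as in the tubule class. Il31ra, an interleukin receptor gene with no control count, was at least 97.8-fold higher, a call that was lost without week 4 library b (adjusted p = 0.052). It was also among the largest rises of the tubule class at this time (12.38 ± 0.93). Tubule RNA was present as well: cluster 19 had 10 of 14 proximal tubule markers at that level, and Cyp4a14, a fatty acid hydroxylase gene, was at least 464-fold higher than in control phagocytes. The largest falls were of genes with no count at week 4, where 3 counts amount to 15.1 CPM. The share of rises was 36.2%, and 60.5% with the relative log expression scaling, so the balance of directions rests on the scaling. The 218 calls became 115 and 102 without control libraries b and c, and 107 and 56 without week 4 libraries a and b.

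Of the 231 planned tests of 21 gene lists in 11 comparisons, camera called 106 with its preset correlation and fry called 70. None of the camera calls holds with an estimated correlation. In 28 of the 231 tests, none of them called by camera, the median or the mean fold change of the list had another sign than the test. Examples are glycolysis at 8 hours (median -0.08, mean 0.90) and hypoxia response at 24 hours (median 0.06, mean -0.46).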

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

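The comparison of week 4 with control with dox was chosen after the results were seen. So were the tests of explanations for how these 2 groups differ from control. The other comparisons of these groups, and the test of free RNA, were chosen before.

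Left and right kidneys at 48 hours differed when the sides were tested against each other, in both cell classes and in 2 cell shares. In the proximal tubule class 119 genes were called. This became 37 and 62 without left libraries b and c and 19, 21 and 54 without right libraries a, b and c. In phagocytes 1098 genes were called, against 613 and 378 without left a and c and 522, 463 and 570 without right a, b and c. Monocyte-like cells had a log2 ratio of left to right shares of 5.05 and neutrophil-like cells of 4.01. Without left library a the ratio of the neutrophil share fell to 2.94 (adjusted p = 0.0838), and its call ended.

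Time points also differed when set against each other. Day 12 and 24 hours differed in 1957 genes of the proximal tubule class, with 1073 and 977 without day 12 libraries a and b and 1109, 1156 and 1165 without 24 hour libraries a, b and c. Week 4 and 24 hours differed in 2783, with 1814 without 24 hour library c and 1258 and 1244 without week 4 libraries a and b. Week 4 and control with dox differed in 5, with 0 and 1 without dox libraries a and b and 3 and 1 without week 4 libraries a and b.

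Cells in clusters that met no rule for a class name were left out of both cell classes tested. They were 23.82% of cells at week 4 and 12.96% in control with dox, against 0.99% in controls, and as a share of cells both were called by edgeR (log2 ratios 4.72 ± 0.57 and 3.82 ± 0.56, adjusted p = 1.42e-06 and 1.78e-05). At 24 hours they were 1.05%, and in left and right kidneys at 48 hours 1.12% and 1%, with no call against control (adjusted p = 0.86, 0.866 and 0.985).

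Week 4 and control with dox each differ from control in many genes of the proximal tubule class. The tables do not separate the counting version from the groups: 5 genes were called between these 2 groups, which share it, so it cannot be told apart from time or doxycycline, the biological explanations the design gives, which stay open and untested. For the falls, a candidate explanation is that cells rich in nuclear RNA lie outside the class: with clusters 44 and 45 added, 15.5% of the 515 week 4 falls were still called as falls and 90 genes were called as rises, the median log2 fold change going from -1.46 to -0.08, and with dox 11.6% of 558 falls were and 122 genes were called as rises, the median going from -1.55 to 0.04. For the 381 rises the values argue against these cells as the whole cause, since 66.4% were still called, 0 were called as falls, and the median went from 1.32 to 1.15 with a median SE of 0.29 before and 0.28 after, and of the 273 rises with dox 62.3% were still called. Introns counted in the Cell Ranger 6.1.2 libraries would raise long genes most, and the rank correlation of gene span with the week 4 fold change was 0.508 with both clusters added, though 0.043 in the class as defined. Esrrg and Fhit, long genes that lead both clusters, were at 14.8 and 9.77 CPM in Malat1-rich control cells. They were at 1524 and 1178 CPM in cluster 44 and at 1744 and 1444 in cluster 45. Camk1d was at most 0.351 CPM in libraries of the older versions and at least 255 in those of 6.1.2. Version and group coincide, so these values do not separate introns from time or doxycycline.

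Proximal tubule rises, in left over right kidneys and at day 12 over control, may hold free RNA of phagocytes, predicted here from the ratio of 6 phagocyte markers between the classes at the lowest, median and highest marker. For genes at 0.1 or more of their level in each other class, 42 rises on the left and 101 at day 12, the prediction reached 50% of the rise in 0% of genes at each ratio, but the choice of genes by level fixed that value, as the marker ratios in these libraries were at most 0.94%, so it decides nothing. For genes below that limit it reached 50% of the rise in 52.4% of 63 genes on the left (1.6% at the lowest ratio) and in 25% of 92 genes at day 12, with 3 markers left out, so it stays open for both sets, as does the state of the tubule cells themselves, which was not tested. At the highest ratio the day 12 value was 7.6%, inside the bound of 10% set in advance against the explanation, but that bound was badly chosen, because the highest ratio also raises the addition predicted for controls and so is no upper limit. Of the markers, C1qb stood at 12.2 ± 10.7 CPM in the tubule class at day 12 against 2.0 ± 1.45 in controls, at 8.19 ± 7.92 and 2.05 ± 2.06 in left and right kidneys, and at 3047 ± 622 CPM in day 12 phagocytes.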

How the results depend on the processing

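Settings that add clusters 44 and 45, leave out the Cell Ranger 6.1.2 libraries, use the shorter feature list alone, pair only the 2 sides, count cluster 37 as dendritic cells or take all barcodes as the total of the shares, and all tests of week 4 against control with dox, were chosen after the data were seen. Values are genes called in the proximal tubule class unless another class is named.

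The call counts moved by less than 1.5 times with relative log expression scaling, the replicate block, doublets kept (gene counts) and the coarser clustering, and without the 6.1.2 libraries (2530 at 8 hours, 3198 at 24 hours, 88 left against right). Other settings moved some. DESeq2 called 9 genes in right kidneys at 48 hours, 285 left against right, 400 at day 12, 13 between week 4 and control with dox, and in phagocytes 1660 left against right and 400 at week 4. With no filter on low counts the counts were 1463 in left and 121 in right kidneys against control, 725 left against right, 1436 at day 6, 796 at day 12, 1329 in control with dox and 118 between week 4 and control with dox. In phagocytes they were 1655 left against right and 533 at week 4. Without the feature-list term 76 were called left against right and 126 at day 12. With only the 2 groups in the fit the counts were 1 at 8 hours, 302 left against right, 1185 at day 6, 2465 at week 4, 1918 in control with dox and 94 between week 4 and control with dox. With proximal tubule-like clusters only they were 1855 at 8 hours and 397 at day 12. At most 25% mitochondrial UMIs left 0 between week 4 and control with dox, and at least 500 genes left 145 in phagocytes at week 4. With doublets kept, 2 class shares were called at day 12 in place of 0. For each of these the cause was not tested.

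With all cells summed, a mix of cell classes, the counts were 959 at 8 hours, 2423 in left kidneys, 1825 left against right, 286 at day 6, 39 at day 12, 2691 at week 4, 6616 for week 4 against 24 hours, 2841 in control with dox and 0 between week 4 and control with dox. With clusters 44 and 45 added they were 3719 at week 4, 5368 for week 4 against 24 hours and 3209 in control with dox. The paired fit of only the 2 sides called 864. The cause of these was not tested. The libraries with the shorter feature list are fewer, with 1 in controls and 2 in each other group they include, so comparisons with control assume that this library varies like the others. They gave 14 at 8 hours, 440 at 24 hours, 0 in left kidneys, 7 left against right, 9 at day 6, 4 at day 12 and 604 for day 12 against 24 hours, and in phagocytes 291 at 24 hours and 493 left against right. Of the 106 gene lists called with the preset correlation, 0 were called with an estimated one, and fry called 67 of them and 70 lists in all.

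Leaving out 1 library, which leaves fewer samples, gave 1707 to 3701 at 8 hours, 2428 to 2767 at 24 hours, 258 to 795 in left kidneys, 0 in right ones, 19 to 129 left against right, 254 to 471 at day 6, 54 to 264 at day 12 and 217 to 630 at week 4. It gave 977 to 1489 for day 12 against 24 hours, 1244 to 2355 for week 4 against 24 hours, 211 to 607 in control with dox and 0 to 3 between week 4 and control with dox. In phagocytes it gave 1056 to 1777 at 24 hours, 378 to 996 left against right and 56 to 237 at week 4. Class shares ran from 1 to 2 left against right, 0 to 3 at day 12, 1 to 5 at week 4 and 2 to 5 in control with dox. The report names each library behind a change over 1.5 times. Where 1 library is left at week 4 or in control with dox, it is assumed to vary like the other groups.

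Single genes and shares changed direction in 29 cases, and the cause was not tested. With all cells summed these were Tgfb1 at 8 hours (-0.02), Atf3 (-0.58) and Pdk1 (1.18) at 24 hours, and Pdk1 for day 12 against 24 hours (-0.58). At week 4 they were Malat1 (0.08), AC149090.1 (0.37), Nfkbiz (0.1) and Pax8 (0.2), and against 24 hours Malat1 (0.13), Pfkl (-0.37), Atf3 (0.17), Pdk1 (-1.08) and Pax8 (0.6). In control with dox they were Ogt (0.07), Pik3c2g (2.28), Slc7a8 (0.17), Cd44 (-0.27), Clu (-0.74), Pax8 (0.7) and Saa3 (0.19). With clusters 44 and 45 added they were Malat1 (0.01), AC149090.1 (0.32), Nfkbiz (0.86) and Pax8 (0.1) at week 4 and Ogt (0.01), Pik3c2g (2.09), Nfkbiz (1.67) and Pax8 (0.51) in control with dox. With at least 500 genes Fgfr2 in phagocytes at week 4 was at -0.08.

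Calls of single genes and shares were otherwise kept, or lost with their direction unchanged. Lost were 7 of 547 with DESeq2, 3 of 547 with relative log expression scaling, 8 of 547 without the filter, 76 of 559 without the feature-list term, 122 of 523 with only the 2 groups in the fit and 1014 of 3174 with 1 library left out. All cells summed lost 145 of 517, and the shorter feature list 319 of 375. The replicate block lost 39 of 559. Of these, 7 were left against right: Gsta4 (adjusted p = 0.0502), Irx3 (0.053), Csad (0.053), Rrm2 (0.0684) and Mcm5 (0.0699) in tubule cells, and H2B-eGFP (0.0556) and Cxcl3 (0.0621) in phagocytes. With only the 2 sides in the paired fit Cyp2a4 (0.26) and Kap (0.0874) were lost in phagocytes. The 9 planned tests of thick ascending limb, principal and endothelial cells were not run, for want of a named cluster or of cells. Depth sets the lowest level that can be seen: 3 counts amount to 0.0512 CPM in the control tubule class and 15.1 CPM in week 4 phagocytes. On simulated data with the depth, number and spread of these libraries 29.9% of 2-fold and 74.2% of 4-fold shifts were called, and depth alone was not varied.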

Other observations

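The splits of libraries and the test of the feature-list version at 8 hours were chosen after the results were seen, and the test of cells of low quality before.

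For each comparison of 3 libraries with 3, the 6 libraries were also split in the 9 other ways, and 10 splits are too few for a share under 0.05. In the proximal tubule class the real split called 2924 genes at 8 hours against at most 130 in another split, 3490 against 1 at 24 hours, 751 against 0 in left kidneys at 48 hours and 119 against 0 between left and right kidneys. It called 648 against 0 at day 6, 209 against 1 at day 12 and 1957 against 0 between day 12 and 24 hours. In phagocytes the values were 2155 against 2 at 24 hours and 1098 against 2 between left and right kidneys. In each of these 1 of the 10 splits, the real one, reached the count, and in right kidneys at 48 hours all 10 did, with 0 called in each. For left against right, where libraries of the same letter correlated, some of the mixed splits put both kidneys of a letter on 1 side. Those splits ignore the possible pairing.

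Gene lists called by camera with its preset correlation behaved otherwise. At 8 hours 4 of the 10 splits called as many lists as the real one, 11 against at most 14 in another split. At 24 hours it was 2 of 10 (14 against 14), in left kidneys at 48 hours 4 (9 against 15) and in right ones 4 (6 against 7). At day 6 it was 4 (10 against 15) and at day 12 2 (11 against 16). Between left and right kidneys 1 split did, the real one (11 against 9), as between day 12 and 24 hours (14 against 12). Splits that mix the groups thus called as many lists or more in 6 of the 8 comparisons. A list call of this kind may reflect genes that vary together between libraries. The counts do not decide this, because each mixed split holds the groups in unequal numbers on its sides and so keeps part of their difference.

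The 8 hour libraries lie farther apart than those of other groups, with a biological coefficient of variation of 0.452 against 0.125 to 0.284 elsewhere. The values argue against the feature-list version as the cause: libraries a and b share a version, and the SD of their log2 difference was 0.796, against 0.229 to 0.479 for 8 same-version pairs of other groups. With at most 25% mitochondrial UMIs the SD was 0.81 against 0.236 to 0.478, which argues against cells of low quality as the cause. The excess lies in the pairs with library a, 0.796 with b and 0.804 with c, since b and c, of different versions, had 0.624, within the 0.51 to 0.68 of such pairs in other groups. No biological explanation was tested.

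The feature lists hold transgenes, which the labels do not mention. Which libraries carry which of them is not given, so differences between groups may also be of genotype. In the proximal tubule class LacZ stood at 0.468 ± 0.319 CPM in controls, 0.493 ± 0.133 at 8 hours (exact permutation p = 1.0), 3.87 ± 1.87 at 24 hours, 5.83 ± 1.57 and 0.46 ± 0.075 in left and right kidneys at 48 hours, 12.8 ± 3.72 at day 6 and 11.5 ± 0.908 at day 12. For 24 hours, day 6 and day 12 against control, and for left against right, the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. The 48 hour sides were not tested against control. At week 4 LacZ had no count, where 3 counts amount to 0.135 CPM. In control with dox it was at 1.97 ± 0.423 CPM (exact permutation p = 0.1 against control, the smallest possible there). Cre was at 0.908 ± 0.787 CPM in controls, 9.42 ± 3.32 at 8 hours and 21.9 ± 13 at 24 hours (exact permutation p = 0.1 for both). H2B-eGFP varied more, at 61.0 ± 72.3 CPM in controls, 578 ± 778 at 24 hours (exact permutation p = 0.2), 0.06 ± 0.105 at day 6 and 357 ± 279 in control with dox (exact permutation p = 0.1). At day 12 it had no count. The rtTA feature was at 11.7 ± 8.08 CPM in controls and 44.6 ± 26.1 at 24 hours (exact permutation p = 0.1).

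As checks, the mean log2(CPM + 1) over the hemoglobin list ran from 0 to 2.65 over the libraries, and over the sex-linked list from 3.06 to 3.99. Dendritic-like cells by the naming rule, all of cluster 36, were 0.6 ± 0.737% of cells in controls and 1.64 ± 1.19% at day 12, and 1.12 ± 1.05% and 4.80 ± 4.11% with cluster 37 counted among them, a setting added after the data were seen. Barcodes with over 50% mitochondrial UMIs, all left out, were 31.9 ± 6.15% of barcodes in controls, 8.57 ± 6.74% in left and 30.5 ± 4.26% in right kidneys at 48 hours, and 10.99 ± 1.07% in control with dox.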
